A study of Danio rerio with 12 samples.

How the data were processed

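The deposited table holds raw counts per Ensembl gene, which the authors made from poly(A) RNA of whole kidney marrow in 12 libraries, 1 per animal. Per the labels' protocols, 100 ng of RNA from each dissected kidney went through poly(A) selection and a directional library kit with 15 PCR cycles, and paired reads of 50 bp were sequenced with 1% PhiX. Per the submitters' processing notes, reads were processed with STAR, Picard and featureCounts on the GRCz10 genome. The tool versions, annotation release, strand setting and treatment of duplicate reads are not given in the sources used here. The kit marks strands, so a count made without the strand would also take in reads of overlapping genes. The labels name no batch, date or sex. Total counts per library ran from 4756244 to 10311377. The 10 genes with most counts took 4.85% to 7.12% of a library.

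Each of the 12 columns was matched to a sample by its genotype and replicate number. Of 32105 identifiers, 26269 matched a symbol in a reference table, and 2592 identifiers repeat a symbol that another also carries. Gene order was taken from a second reference table, which is on the GRCz12tu assembly and not on GRCz10, so no coordinates are given. The labels do not say that the replicate numbers pair animals across groups. Of 18 pairs with the same number, 6 had a correlation above 0.1 after group means were removed, with a median of 0.066 against -0.017 for other pairs, so no pairing term was used in the comparisons reported first. All 3 pairs of il2rga with double mutants were above 0.1 (0.132, 0.121 and 0.518), and the value with the replicate number as a block is given beside that comparison. Counts of replicates differed by far more than duplicates of 1 library would, with chi-square values per degree of freedom of 19.8 to 83.2.

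Genes were kept by filterByExpr, which left 18370, and scaled by TMM. edgeR 4.0.16 in R 4.3.3 fitted all 12 libraries with 4 group means (glmQLFit with robust estimates), so that the groups share 1 estimate of the spread, and glmQLFTest gave 2-sided tests of 6 pairs of groups and of the interaction, the double minus il2rga difference less the prkdc minus wild type difference. The Benjamini-Hochberg adjustment was made over all genes within a comparison at 0.05. The common biological coefficient of variation was 0.418. Log2 CPM used a prior count of 2. The standard error is the log2 fold change divided by the root of the F statistic.

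Before the data were examined, 37 gene lists were written for blood and immune cells, kidney cells, other tissues and cell processes. After matching, 36 had at least 3 tested members and were tested by fry from limma 3.58.1, adjusted by Benjamini-Hochberg over the lists of a comparison. fry asks whether a list's genes move on balance in 1 direction, and compares a list with no other genes. camera with an estimated and with a preset correlation of 0.01 was run beside it, and the adjusted p with an estimated correlation is given for each list called. Of the calls of these 36 lists, those of T cells and immunoglobulins in prkdc mutants and of T cells and cytotoxic cells in il2rga mutants against wild type hold with an estimated correlation, and the others do not. Many paralogue symbols of the lists were absent from the reference table. From lists written with a name stem, 15 genes that share the stem but not the family were removed. The list of very long transcripts was written after long genes had been seen among the falls, and its p was adjusted over the 7 comparisons. That p comes from the libraries that prompted the list, so it is not an independent test.

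The genes named follow a rule fixed beforehand: the targeted genes, the 8 largest changes per direction in each mutant against wild type and 4 in the other comparisons, and up to 4 called members of each list by smallest p, or otherwise its most abundant member. The largest changes were taken among called genes with a mean of at least 1 CPM, no overlap between the groups and a gene symbol that is not a clone name. Others are marked where they appear as chosen after their values were seen. Lists were also read "adjusted over the list alone", with the adjustment made over their own members.

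Alternatives fixed before the data were examined were DESeq2 size factors in edgeR, no filter, a filter of 1 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, limma voom with quality weights, only the groups compared, the replicate number as a block, no haemoglobin genes, a kidney tubule covariate, both camera tests and leaving out each library in turn. A liver covariate and leaving out the 4 libraries richest in liver transcripts were added after the data were seen. Scaling left the median log2 fold change of all genes within 0.1 of 0 under each setting, except -0.107 for double against prkdc mutants without those 4 libraries. The overlap between mutants was set against 40 simulations of unchanged groups with the same wild type libraries, and 100 regroupings of the libraries were fitted.

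The steps were tested on simulated data with 12 libraries of 18370 genes at the same depths and spread, in which 50 genes each changed 2-fold, 4-fold, 8-fold and 16-fold. In 3 comparisons with wild type, 4% to 8% of the 2-fold, 44% to 64% of the 4-fold, 68% to 76% of the 8-fold and 86% to 92% of the 16-fold changes were called, with 0 to 5 wrong calls among 18020 unchanged genes. All 10 changed lists were called in each, with 1 wrong call at most among 20 unchanged lists. Each gene was drawn on its own, and every member of a changed list fell 2-fold. The simulated lists thus had no correlation between genes, so power and error for lists whose genes move together were not tested. Single-cell libraries of the same study were not analysed here.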

Results

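Poly(A) RNA was sequenced from the whole kidney marrow of zebrafish, the blood-forming tissue of the fish, which lies among the kidney tubules. Each library came from the kidney of a single animal. The 12 libraries fell into 4 groups of 3 animals: wild type, prkdc mutant, il2rga mutant and double mutant. The gene prkdc encodes the catalytic subunit of the DNA-dependent protein kinase, which joins DNA ends while antigen receptor genes are assembled. The gene il2rga encodes the common gamma chain, a receptor subunit shared by several interleukins that act on lymphocytes. The series set these immunodeficient animals beside wild type to learn which blood lineages each lacks. Total counts were 10311377, 8234272 and 8864689 in wild type 1 to 3, and 8415980, 9465242 and 7865665 in prkdc mutant 1 to 3. They were 4756244, 8907049 and 5112787 in il2rga mutant 1 to 3, and 9220273, 9909915 and 6854963 in double mutant 1 to 3. Of 32105 genes in the table, 18370 had enough counts to be tested. Levels are given as CPM, counts scaled to the size of the library, with the SD of 3 libraries, and log2 fold changes with the standard error of the fit. Folds against a group with no counts were set against a floor of 3 counts over that group, and ratios with 1 to 3 counts carry a 95% interval. Such intervals and floors cover counting error only.

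The level of il2rga followed the labels in every library. It (ENSDARG00000068858) stood at 47.4 ± 12.4 CPM in wild type, 37.3 ± 4.30 CPM in prkdc mutants, 4.24 ± 2.29 CPM in il2rga mutants and 2.78 ± 1.07 CPM in double mutants. It fell against wild type by 3.52 ± 0.44 in il2rga mutants (log2, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00473) and by 4.07 ± 0.44 in double mutants (adjusted p = 0.00215). The 6 libraries labelled with the il2rga mutation lay between 1.71 and 6.17 CPM, and the other 6 between 34.1 and 61.4 CPM. prkdc (ENSDARG00000075083) stood at 55.7 ± 6.54 CPM in wild type, 20.5 ± 3.90 CPM in prkdc mutants, 29.6 ± 6.52 CPM in il2rga mutants and 18.6 ± 0.707 CPM in double mutants. Its log2 fold change was -1.44 ± 0.22 in prkdc mutants, which did not pass adjustment over all genes in edgeR (adjusted p = 0.117), although all 3 libraries lay below all 3 of wild type. It fell by 1.58 ± 0.22 in double mutants (adjusted p = 0.0043). It also fell by 0.91 ± 0.21 in il2rga mutants, whose prkdc is not the targeted gene (adjusted p = 0.0339 in edgeR). The library of il2rga mutant 3, at 22.1 CPM, lay inside the 16 to 23.3 CPM of the prkdc mutants. prkdc has a very long transcript, and other very long transcripts fell in the same libraries.

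**Figure D1:**
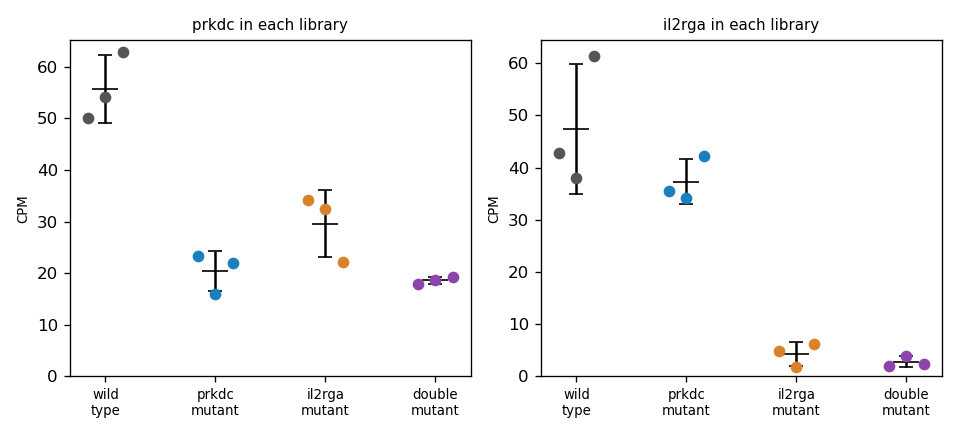
CPM of prkdc and il2rga on linear axes from 0, with 1 point per library and bars at the mean ± SD of the 3 libraries of each genotype. il2rga lies at or below 6.17 CPM in the 6 libraries with its mutation, and prkdc is highest in wild type, at 50.1 to 62.8 CPM.

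Liver transcripts were high in 5 of the 6 libraries with the il2rga mutation, and very long transcripts were low in all 6. The mean of the 16 liver genes, which include fibrinogen and transferrin, was 1.61 ± 0.56 log2 CPM in wild type and 1.17 ± 0.30 in prkdc mutants. It was 5.95, 7.29 and 1.68 in il2rga mutant 1 to 3 and 8.63, 6.53 and 5.29 in double mutant 1 to 3. The fibrinogen chain fga stood at 2015 CPM in double mutant 1 and at 2.95 CPM or less in all wild type libraries. The ovary and vitellogenin list, genes of the egg coat and of yolk, reached 7.27 in double mutant 1 and 4.13 in double mutant 2, against 1.21 or less in wild type and prkdc mutants, and was 2.36, 2.103 and -0.59 in il2rga mutant 1 to 3 and 0.17 in double mutant 3. The testis list did not follow genotype, with 4.47 in il2rga mutant 2, 1.59 in prkdc mutant 2 and -0.97 in double mutant 3. The labels do not give the sex of the animals, so its part in the ovary and testis lists was not tested. A list of 53 very long transcripts with unrelated functions, drawn up after long genes had been noticed among the falls, had a mean of 5.85 ± 0.046 in wild type and 5.74 ± 0.12 in prkdc mutants. It was 5.01 ± 0.26 in il2rga mutants and 5.0 ± 0.12 in double mutants (log2 CPM, n = 3 each). The p values given below for this list come from the libraries that prompted it, so they are not an independent test. The first principal component, with 41.7% of the variance, placed wild type and prkdc mutants between -67.5 and -42.2. The il2rga mutants lay at 53.9, 79.0 and -13.9, and the double mutants at 145, 88.8 and 3.19.

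**Figure D2:**
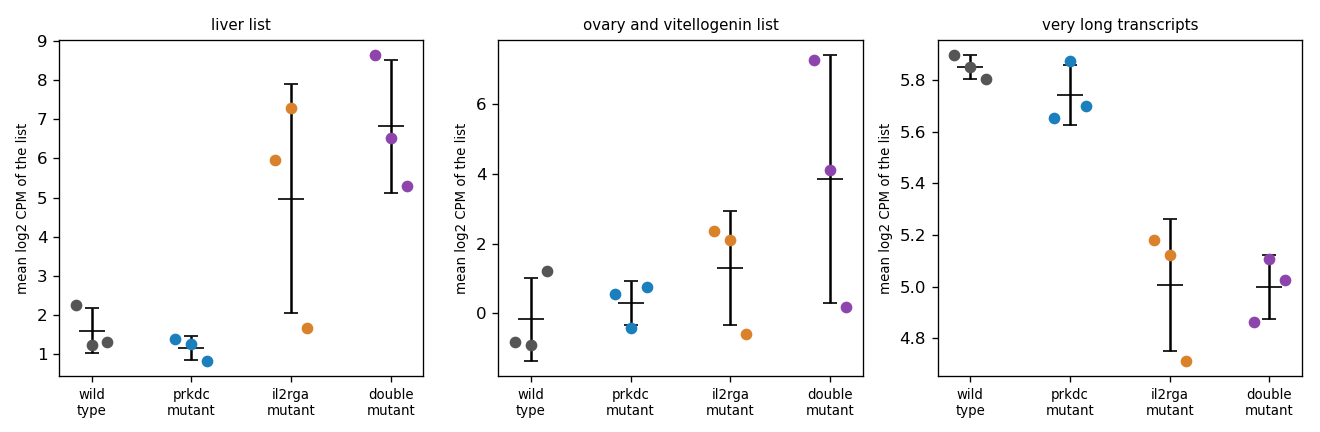
Mean log2 CPM of the liver list, the ovary and vitellogenin list and the list of very long transcripts, with 1 point per library and bars at the mean ± SD of the 3 libraries of each genotype. Liver transcripts are above 5 in 5 of the 6 libraries with the il2rga mutation, and very long transcripts are below 5.2 in all 6.

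The prkdc mutants were compared with wild type to learn which lineages need the kinase that joins antigen receptor genes. Markers of T cells and immunoglobulin genes fell together. The T cell list, 16 genes of T cell receptor signalling and migration, had a mean of 2.53 ± 0.43 log2 CPM in wild type and 0.92 ± 0.44 in prkdc mutants, with a median log2 fold change of -1.59. It passed the fry test over lists (adjusted p = 0.0456, and adjusted p = 0.0387 with an estimated correlation). The 9 immunoglobulin genes went from 2.26 ± 0.88 to -0.64 ± 0.38, with a median of -4.15 (fry, adjusted p = 0.0469, and adjusted p = 0.0387 with an estimated correlation). Every prkdc mutant library lay below every wild type library in both lists. Adjusted over the list alone, 7 T cell genes and all 9 immunoglobulin genes fell, while over all genes tested 0 did. The B cell list had a median of -2.04 and did not pass (fry, adjusted p = 0.158), with 7 members that fell and 1 that rose when adjusted over the list alone. The cytotoxic T and NK cell list, genes of granule killing, had a median of -0.32 (fry, adjusted p = 0.313).

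Single genes in prkdc mutants did not pass adjustment, and those given here, apart from zap70 and ighm, were chosen after their values were seen. The chemokine receptor ccr7, which guides T cells into lymphoid tissue, had a log2 fold change of -4.03 ± 0.50 (edgeR, adjusted p = 0.0604). The T cell transcription factor tcf7 had -3.74 ± 0.54 (adjusted p = 0.101), and the T cell receptor kinase zap70 had -1.98 ± 0.61 (adjusted p = 0.6). The B cell factor pax5 had -4.49 ± 0.80 (adjusted p = 0.214), and the B cell receptor subunit cd79a had -3.77 ± 0.70 (adjusted p = 0.225). The immunoglobulin heavy chain ighm stood at 88.0 ± 30.8 CPM in wild type and 14.7 ± 3.51 CPM in prkdc mutants. The immunoglobulin light chain gene igic1s1 had 3 counts in prkdc mutants and 196 in wild type, a ratio of 61.4 (20.7 to 300.2). The killing genes nkl.4 and prf1.9 had log2 fold changes of 0.42 and 0.56, with 304 and 135 counts in prkdc mutants against 245 and 98 in wild type. Over all 18370 genes, edgeR called 0 at an adjusted p under 0.05, the DESeq2 Wald test 139 and limma voom with quality weights 26, and 1052 had an unadjusted p under 0.05 in edgeR where chance gives 918. The edgeR count was 5 without wild type 2, 1 without wild type 3, 3 without prkdc mutant 1 and 4 without il2rga mutant 2. Neither list passed without wild type 1, wild type 2, any 1 prkdc mutant, il2rga mutant 1 or any 1 double mutant. Nor did either pass without the 4 libraries richest in liver transcripts, which are il2rga and double mutants. The wild type and prkdc mutant libraries compared were the same there. The most lists, 3, passed without il2rga mutant 3.

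The il2rga mutants were compared with wild type to learn which lineages need the common gamma chain. Genes of T cells and of cytotoxic T and NK cells fell, while B cell and immunoglobulin genes as groups did not pass. The T cell list went from 2.53 ± 0.43 to -0.46 ± 0.38 log2 CPM, and 11 of its 16 members fell over all genes tested and 13 adjusted over the list alone (median -3.67, fry, adjusted p = 0.000886, and adjusted p = 0.0427 with an estimated correlation). The cytotoxic T and NK cell list went from 2.17 ± 0.29 to -0.16 ± 0.11, and 10 of its 16 members fell over all genes tested and 11 adjusted over the list alone. Its median was -3.64, or -3.01 with genes at 0 counts held at their bound (fry, adjusted p = 0.000338, and adjusted p = 0.0226 with an estimated correlation). All 3 il2rga mutant libraries lay below all 3 of wild type in both lists. ccr7 fell by 4.95 ± 0.55 (edgeR, adjusted p = 0.00285), the adaptor lat by 4.91 ± 0.63 (adjusted p = 0.00473) and the T cell kinase itk by 4.93 ± 0.75 (adjusted p = 0.00909). The T cell receptor constant gene trbc1 fell by 5.80 ± 0.87 (adjusted p = 0.00809). The T cell factor bcl11ba fell to 1 count against 164, a ratio of 112 (19.9 to 4464).

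Killing genes fell with them. The granzyme gzma fell by 4.43 ± 0.55 (edgeR, adjusted p = 0.00473), the lymphocyte factor tbx21 by 3.16 ± 0.54 (adjusted p = 0.0115) and the interleukin receptor subunit il2rb by 2.52 ± 0.48 (adjusted p = 0.016). The NK-lysins nkl.4 and nkl.2 fell to 3 and 2 counts, with ratios to wild type of 55.9 (18.9 to 273) and 44.5 (12.1 to 372). The chemokines ccl34b.4 and ccl33.3 fell by 6.07 ± 0.84 and 4.60 ± 0.81 (adjusted p = 0.00584 and 0.0129), and cxcl32b.1 was at least 26.3-fold lower. Among B cell genes, cd79a stood at 13.8 ± 7.50 CPM in wild type and 16.1 ± 9.08 CPM in il2rga mutants. The B cell list had a median of -0.13 (fry, adjusted p = 0.78), and its member cd22, an inhibitory receptor, rose by 2.00 ± 0.49 (edgeR, adjusted p = 0.0376). The immunoglobulin list had a median of 0.55 (fry, adjusted p = 0.73), and ighm stood at 254 ± 294 CPM.

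**Figure D3:**
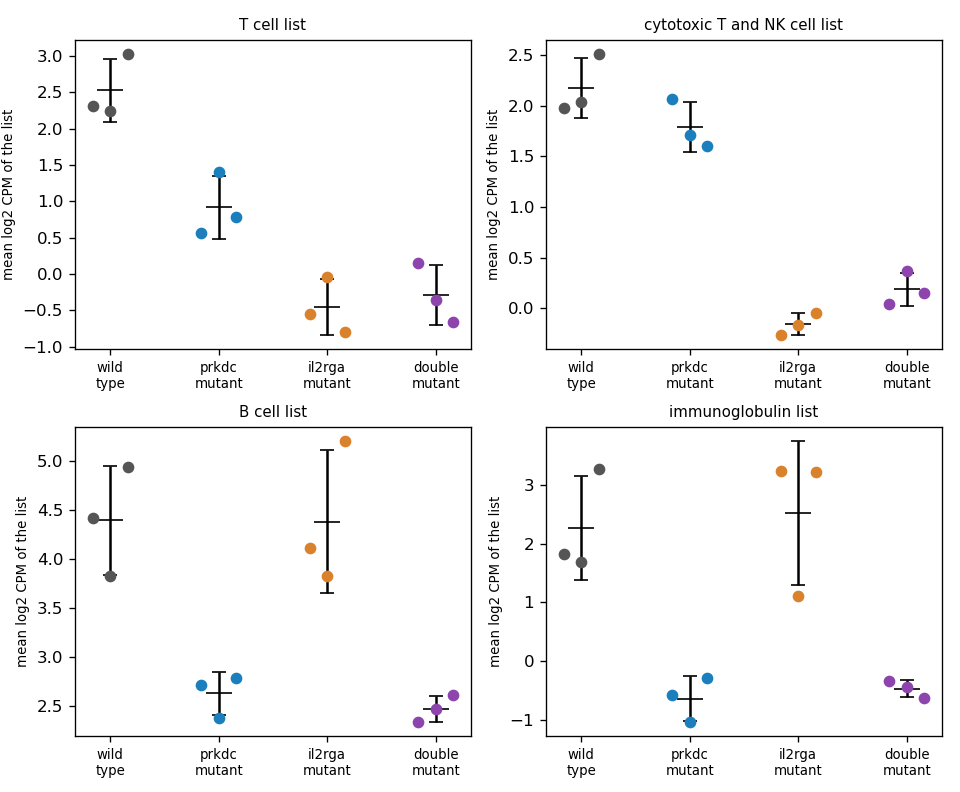
Mean log2 CPM of the T cell, cytotoxic T and NK cell, B cell and immunoglobulin lists, 1 list per panel on its own scale, with 1 point per library and bars at the mean ± SD of the 3 libraries of each genotype. T cell means are 2.53 in wild type, 0.92 in prkdc mutants, -0.46 in il2rga mutants and -0.29 in double mutants, and immunoglobulin means are 2.26, -0.64, 2.52 and -0.47.

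Among the 8 largest rises in il2rga mutants under the naming rule, the interleukin il11a had 0 counts in wild type and was at least 27.1-fold higher. The C-type lectin illr3 rose by 6.32 ± 0.93 (edgeR, adjusted p = 0.00748), the class I gene mhc1uba by 6.55 ± 1.4 (adjusted p = 0.028) and the inflammatory caspase caspb by 4.66 ± 1.03 (adjusted p = 0.0287). For mhc1uba, a haplotype that differs from the reference genome was not tested as the source. The complement component c9 rose by 6.6 ± 1.53 (adjusted p = 0.0363) and the ketone body enzyme oxct1b by 5.13 ± 1.32 (adjusted p = 0.0474). otogl and the hepatic lipase lipc had 2 and 1 counts in wild type, and ratios of 117 (31.8 to 973) and 187 (32.9 to 7438). Under that rule all 3 mutant libraries lie on 1 side of all 3 of wild type, which chance gives for 10% of genes. Of the 16 liver genes, 2 rose over all genes tested and 14 adjusted over the list alone, with a median of 4.96 (fry, adjusted p = 0.22). Of the 53 very long transcripts 19 fell and 0 rose, with a median of -0.85 (fry, adjusted p = 0.000225 over the 7 comparisons, and adjusted p = 0.0288 with an estimated correlation). Falls in these same libraries prompted that list.

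In all, edgeR called 1066 genes in il2rga mutants, 407 higher and 659 lower, and 772 of them differed by at least 2-fold. Unadjusted, 4368 genes had p under 0.05. The count was 322, 342 and 160 without wild type 1, 2 and 3, 652 without prkdc mutant 3, and 656 and 295 without il2rga mutant 1 and 2. With the liver list as a covariate it was 15, with all 1066 keeping their sign, and without the 4 libraries richest in liver transcripts, which leaves 1 il2rga mutant, it was 22, with 1059 of the 1066 keeping theirs. Of the lists, 2 passed, and 4 without il2rga mutant 3 or double mutant 3. Without the 4 libraries the T cell and cytotoxic lists did not pass (fry, adjusted p = 0.065 each), though the il2rga mutant left, il2rga mutant 3, stood at -0.80 and -0.043 log2 CPM, far below the wild type means of 2.53 and 2.17.

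The double mutants were compared with wild type to learn what is missing when both genes are lost. The lists of T cell, cytotoxic, B cell and immunoglobulin genes passed downward in fry, and none of the 4 passed with an estimated correlation. The T cell list had a mean of -0.29 ± 0.41 log2 CPM, and 12 of 16 members fell over all genes tested and 13 adjusted over the list alone (median -3.47, fry, adjusted p = 0.00101, and adjusted p = 0.108 with an estimated correlation). The cytotoxic T and NK cell list had a mean of 0.19 ± 0.16, and 8 of 16 fell over all genes tested and 11 adjusted over the list alone (median -2.19, fry, adjusted p = 0.000346, and adjusted p = 0.0543 with an estimated correlation). The B cell list had a mean of 2.47 ± 0.14 against 4.40 ± 0.56 in wild type, and 5 of 11 members fell over all genes tested and 6 adjusted over the list alone. Its median was -0.96 and its mean fold -2.48 (fry, adjusted p = 0.0438, and adjusted p = 0.646 with an estimated correlation). The immunoglobulin list had a mean of -0.47 ± 0.14, and 7 of 9 members fell over all genes tested and 8 adjusted over the list alone. Its median was -5.07, or -3.93 with genes at 0 counts held at their bound (fry, adjusted p = 0.0438, and adjusted p = 0.646 with an estimated correlation). In each of these 4 lists all double mutant libraries lay below all wild type libraries.

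Among T cell genes of the double mutants, ccr7 fell by 5.19 ± 0.54 (edgeR, adjusted p = 0.00188), themis, needed for T cell development, by 5.24 ± 0.81 (adjusted p = 0.00555), lat by 4.20 ± 0.57 (adjusted p = 0.00423) and itk by 4.50 ± 0.71 (adjusted p = 0.00591). trbc1 and the regulatory T cell factor foxp3a fell to 3 and 1 counts, with ratios of 107 (36.2 to 521) and 81.5 (14.2 to 3257). Among cytotoxic genes tbx21 fell by 3.93 ± 0.56 (adjusted p = 0.00474), gzma by 3.22 ± 0.48 (adjusted p = 0.00517) and nkl.2 by 4.79 ± 0.73 (adjusted p = 0.00535), and the perforin prf1.9 had 3 counts and a ratio of 31.0 (10.29 to 153). Among B cell genes pax5 fell by 5.03 ± 0.84 (adjusted p = 0.00694), cd79a by 4.28 ± 0.73 (adjusted p = 0.00728) and the tetraspanin cd37 by 4.97 ± 0.97 (adjusted p = 0.0135). cxcr5, which guides B cells to follicles, had 0 counts in double mutants and was at least 39.9-fold lower. ighm fell by 3.37 ± 0.78 (adjusted p = 0.0236), and the light chains igl3c3 and igl1c3 had 1 and 2 counts, with ratios of 84.4 (14.8 to 3370) and 65.4 (17.8 to 546). irf4b, a factor of plasma cell formation, fell to 3 counts, a ratio of 48.7 (16.3 to 239). It was the 1 member of 3 in the plasma cell list that fell, over all genes tested and adjusted over the list alone, so the list passed downward in fry although its median was 0.21 and its mean -1.56 (adjusted p = 0.0438, and adjusted p = 0.736 with an estimated correlation). The list of DNA end joining genes passed upward with a median of 0.54 and 0 of 9 members called over all genes tested or adjusted over the list alone (fry, adjusted p = 0.0438, and adjusted p = 0.736 with an estimated correlation).

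The largest rises in double mutants were blood plasma and yolk proteins made by the liver. The fibrinogen chains fga and fgg rose by 9.10 ± 2.16 and 9.01 ± 2.21 (edgeR, adjusted p = 0.026 and 0.0286), angiotensinogen agt by 9.83 ± 2.68 (adjusted p = 0.0385), the complement gene c3a.2 by 8.49 ± 2.05 (adjusted p = 0.0274) and the vitellogenin vtg7 by 9.02 ± 2.49 (adjusted p = 0.0398). The apolipoprotein apoa4b.2 and clotting factor f9 had 0 counts in wild type and were at least 128-fold and 122-fold higher, and itih3a.1 had 1 count and a ratio of 547 (97.8 to 21665). Of the 16 liver genes 13 rose over all genes tested and 15 adjusted over the list alone (median 6.88, fry, adjusted p = 0.0645). Of the 21 ovary and vitellogenin genes 4 rose over all genes tested and 20 adjusted over the list alone (median 5.60, fry, adjusted p = 0.15). With the liver list as a covariate fga, fgg, c3a.2 and vtg7 had values below 0, none of which passed (edgeR, adjusted p from 0.738 to 0.866). fga and fgg are members of that list, so the covariate takes out their change by construction. Of the 53 very long transcripts 24 fell and 0 rose, with a median of -0.82 (fry, adjusted p = 0.000225 over the 7 comparisons, and adjusted p = 0.0288 with an estimated correlation). Here too the list was prompted by falls in the same libraries.

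In all, edgeR called 2628 genes in double mutants, 1249 higher and 1379 lower, and 1908 of them differed by at least 2-fold. Unadjusted, 5947 genes had p under 0.05. The count was 715, 1240 and 490 without wild type 1, 2 and 3, 1703 without prkdc mutant 3 and 509 without double mutant 1. It was 0 in edgeR with the liver list as a covariate, and 0 without the 4 libraries richest in liver transcripts, which leaves 1 double mutant, while 2481 and 2490 of the 2628 kept their sign. The DESeq2 Wald test on all libraries called 4078 genes and limma voom 2975. Of the 6 lists that passed, those of T cells and cytotoxic cells also passed without any 1 library. They alone of the 6 passed without wild type 1, wild type 3, any 1 prkdc mutant, il2rga mutant 1 or double mutant 3. The B cell list passed with them without wild type 2, the end joining list without double mutant 1 or 2, and all but the plasma cell list without il2rga mutant 3. With the liver covariate only the T cell list passed (fry, adjusted p = 0.0347). Without the 4 libraries the T cell, cytotoxic, B cell, immunoglobulin and plasma cell lists no longer passed. Double mutant 3, the 1 double mutant then left, stood at -0.66, 0.15, 2.61 and -0.63 log2 CPM in the first 4. The wild type means were 2.53, 2.17, 4.40 and 2.26.

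The double mutants were compared with prkdc mutants to learn what loss of the common gamma chain adds when prkdc is already lost. The cytotoxic T and NK cell list passed downward in fry, but not with an estimated correlation or with the liver covariate. It went from 1.79 ± 0.24 to 0.19 ± 0.16 log2 CPM, and 10 members fell and 1 rose over all genes tested, as they did adjusted over the list alone. Its median was -2.19 (fry, adjusted p = 0.0011, and adjusted p = 0.145 with an estimated correlation). nkl.2 fell by 4.49 ± 0.73 (edgeR, adjusted p = 0.00805) and tbx21 by 3.11 ± 0.55 (adjusted p = 0.01). prf1.9 fell to 3 counts, a ratio of 45.4 (15.2 to 223), and prf1.1 had 0 counts and was at least 9.51-fold lower. The member that rose, prf1.6, another perforin, had 3.12 ± 0.86 (adjusted p = 0.0365) and was chosen after its values were seen. In the T cell list themis fell by 3.02 ± 0.81, the kinase lck by 2.53 ± 0.69 and lat by 1.9 ± 0.56 (adjusted p = 0.0332, 0.0361 and 0.0455), 7 members fell adjusted over the list alone, and the list had a median of -1.64, or -1.52 with genes at 0 counts held at their bound (fry, adjusted p = 0.0525). The B cell and immunoglobulin lists had medians of -0.43 and -0.020 (fry, adjusted p = 0.686 and 0.852).

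Of the 25 genes of the proliferation list, 12 rose in double mutants against prkdc mutants over all genes tested and 14 adjusted over the list alone, and the list did not pass, with a median of 1.27 (fry, adjusted p = 0.0609). Against wild type its median in prkdc mutants was -0.89, with all 25 genes below 0 (fry, adjusted p = 0.454). The mitotic kinases aurkb and plk1 rose by 2.36 ± 0.41 and 2.74 ± 0.50 (edgeR, adjusted p = 0.00981 and 0.011), and cdc20, which starts anaphase, by 2.93 ± 0.53 (adjusted p = 0.0107). Double mutant 1 was highest both in this list, at 7.39 log2 CPM, and in the ovary and vitellogenin list, whose median in this comparison was 5.91 (fry, adjusted p = 0.242). The 4 largest rises under the naming rule were psmb8, selenop2, psmb13a and tmem144, at least 450-fold, 355-fold, 221-fold and 212-fold higher than the 0 counts in prkdc mutants. The immunoproteasome genes psmb8 and psmb13a had no counts in any prkdc mutant. They were also at 0.108 and 0 CPM in wild type 3, while every double mutant, which shares the prkdc mutation, had them. Of the largest falls, fer1l4 and sptssb had -7.21 ± 1.36 and -7.07 ± 1.4 (edgeR, adjusted p = 0.0135 and 0.0153), and c1qtnf13 was at least 23.5-fold lower. Of the 16 liver genes 13 rose over all genes tested and 15 adjusted over the list alone (median 7.64, fry, adjusted p = 0.0644), and 15 of the 53 very long transcripts fell (median -0.78, fry, adjusted p = 0.000325 over the 7 comparisons, and adjusted p = 0.0333 with an estimated correlation). In all, edgeR called 2717 genes, 1456 higher and 1261 lower, 2016 by at least 2-fold. The count was 1344, 829 and 400 without prkdc mutant 1, 2 and 3 and 382 without double mutant 1. With the liver covariate and without the 4 libraries richest in liver transcripts edgeR called 0, and 2527 and 2587 of the 2717 kept their sign, against 5928 with an unadjusted p under 0.05 on all libraries, 4176 called by DESeq2 and 3396 by limma voom. The lists that passed were 4 without il2rga mutant 3, 2 without double mutant 1 and 3 without double mutant 2 or 3. With the liver covariate 0 of 36 passed in fry, and the cytotoxic list did not pass with it (adjusted p = 0.242) or without the 4 libraries. Double mutant 3, the 1 double mutant then left, stood at 0.15 log2 CPM in that list, against a mean of 1.79 in prkdc mutants.

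The double mutants were compared with il2rga mutants to learn what loss of prkdc adds when the common gamma chain is already lost. In the fit without the replicate number no gene and no list passed, and the lists with the smallest p included those of B cells and immunoglobulins. With the replicate number as a block 5 genes fell, among them cd79a, cd79b and pax5 by 4.41, 3.44 and 4.71 (edgeR), as did the B cell, immunoglobulin and plasma cell lists (fry, adjusted p = 0.00669, 0.011 and 0.011). The immunoglobulin list stood at 2.52 ± 1.23 log2 CPM in il2rga mutants and -0.47 ± 0.14 in double mutants, with a median log2 fold change of -4.90, or -4.17 with genes at 0 counts held at their bound, and the B cell list at 4.38 ± 0.73 and 2.47 ± 0.14, with a median of -1.13. Each had a fry adjusted p of 0.0516, as did the plasma cell list, whose median was 0.080 and mean -1.67. Adjusted over the list alone, 8 immunoglobulin, 7 B cell and 1 plasma cell gene fell. Every double mutant library lay below every il2rga mutant library in the B cell and immunoglobulin lists. irf4b had the smallest adjusted p of all genes, 0.110 in edgeR, with 3 counts in double mutants against 83, a ratio of 38.3 (12.7 to 189). ighm had -4.90 ± 0.83, cd79a -4.49 ± 0.74, pax5 -4.82 ± 0.85 and igic1s1 -6.26 ± 1.09 (edgeR, adjusted p = 0.236, 0.216, 0.236 and 0.236), and all but ighm of these 5 were chosen after their values were seen. The T cell and cytotoxic lists had medians of 0.25, or 0.34 without a gene at or near 0 counts in both groups, and 0.35 (fry, adjusted p = 0.862 and 0.6). Liver and very long transcripts had medians of 1.34 (fry, adjusted p = 0.6) and -0.028 (fry, adjusted p = 0.952 over the 7 comparisons). edgeR called 0 genes and limma voom 0, DESeq2 called 72, and 1767 had an unadjusted p under 0.05 in edgeR. Without il2rga mutant 2 edgeR called 5, and 3 lists passed without wild type 3 or il2rga mutant 2.

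The il2rga mutants were compared with prkdc mutants to learn how the lineages lost differ between the 2 genes. In fry the immunoglobulin list was higher in il2rga mutants and the T cell and cytotoxic lists were lower, and none of the 3 passed with an estimated correlation. Of 9 immunoglobulin genes 5 rose over all genes tested and 8 adjusted over the list alone, with a median of 4.25 (fry, adjusted p = 0.0269, and adjusted p = 0.306 with an estimated correlation). ighm rose by 4.11 ± 0.80 (edgeR, adjusted p = 0.0198) and ighd by 2.70 ± 0.58 (adjusted p = 0.0263), and igic1s1 and igl1c3 had 3 and 2 counts in prkdc mutants, with ratios of 112 (37.9 to 547) and 77.5 (20.96 to 648). Of 11 B cell genes cd79a, pax5 and cd37 rose, by 3.98 ± 0.71, 4.28 ± 0.80 and 5.18 ± 0.99 (adjusted p = 0.0133, 0.0156 and 0.0179), 5 rose adjusted over the list alone, and the list had a median of 1.36 (fry, adjusted p = 0.0536). irf4b rose by 2.59 ± 0.54 (adjusted p = 0.024). In the cytotoxic T and NK cell list 7 members fell and 1 rose over all genes tested, and 11 fell and 1 rose adjusted over the list alone, with a median of -2.09 (fry, adjusted p = 0.000837, and adjusted p = 0.0619 with an estimated correlation). nkl.3 fell by 5.22 ± 0.88 and ccl33.3 by 5.15 ± 0.82 (edgeR, adjusted p = 0.0109 and 0.00958), and the member that rose was prf1.6, 3.25 ± 0.87 (adjusted p = 0.0488), chosen after its values were seen. In the T cell list 2 members fell over all genes tested, lat by 2.62 ± 0.63 (edgeR, adjusted p = 0.037) and bcl11ba with 1 count and a ratio of 21.9 (3.64 to 893), and 10 adjusted over the list alone. Its median was -2.19, or -1.97 with genes at 0 counts held at their bound (fry, adjusted p = 0.0369, and adjusted p = 0.459 with an estimated correlation).

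The p53 target list was higher in il2rga mutants than in prkdc mutants, with a median of 0.39 (fry, adjusted p = 0.0238, and adjusted p = 0.306 with an estimated correlation). Its 2 members that rose, over all genes tested and adjusted over the list alone, were rps27l, a relative of a ribosomal protein, by 1.17 ± 0.21 and gtse1, a gene of dividing cells, by 1.46 (edgeR, adjusted p = 0.0139 and 0.0465). In this comparison the ribosomal protein and proliferation lists, which did not pass in fry, had medians of 0.37 and 0.88. A median of this size was thus not particular to p53 targets. The largest rises under the naming rule were psmb8, psmb13a, psmb12 and illr1, at least 709-fold, 341-fold, 314-fold and 119-fold. In wild type 3 psmb8, psmb13a and psmb12 were also at 0.108, 0 and 0 CPM, while every double mutant had them. The largest falls included nkl.4, with 3 counts against 304, a ratio of 73.9 (25.05 to 360), and cxcl32b.1, at least 13.7-fold. Of the 16 liver genes 6 rose over all genes tested and 14 adjusted over the list alone (median 6.13, fry, adjusted p = 0.132), and 14 of the 53 very long transcripts fell (median -0.70, fry, adjusted p = 0.000325 over the 7 comparisons, and adjusted p = 0.0288 with an estimated correlation). In all, edgeR called 1244 genes, 570 higher and 674 lower, 894 by at least 2-fold, and 4806 had an unadjusted p under 0.05. The count was 814, 703 and 671 without wild type 1, 2 and 3, 580, 459 and 191 without prkdc mutant 1, 2 and 3, and 524, 388 and 686 without il2rga mutant 1, 2 and 3. It was 4 with the liver covariate and 16 without the 4 libraries richest in liver transcripts, with 1241 and 1226 of the 1244 keeping their sign. Of these 4 lists, 3 passed without il2rga mutant 3, 2 without wild type 1 or prkdc mutant 1, and 1 without prkdc mutant 2, prkdc mutant 3 or il2rga mutant 1.

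The interaction asks whether the change in double mutants differed from the sum of the changes in the single mutants. No gene and no list passed. The T cell list had a median of 1.72 (fry, adjusted p = 0.283), with 4 members that rose adjusted over the list alone and 0 over all genes tested. ccr7 and tcf7, chosen after their values were seen, had 3.78 ± 0.78 and 4.28 ± 0.78 (edgeR, adjusted p = 0.788 each). The T cell list already stood at -0.46 log2 CPM in il2rga mutants, and at -0.29 in double mutants. Its member trbc1 had 4 and 3 counts there. A further fall could hardly show at such levels, so positive values in this list cannot be read as a departure from the sum. ighm had -2.31 ± 1.02 and the cytotoxic list a median of 0.93 (fry, adjusted p = 0.283 for the list). The proliferation list had a median of 1.27 (fry, adjusted p = 0.52). edgeR called 0 genes and limma voom 0, DESeq2 called 49, and 1123 had an unadjusted p under 0.05 in edgeR where chance gives 918. Without prkdc mutant 1 edgeR called 1.

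The il2rga and double mutants shared most of the calls of the il2rga mutants. In both, 840 genes were called in the same direction against wild type, 303 higher and 537 lower, where independent calls give 77.1, and 0 in opposite directions. Their log2 fold changes had a correlation of 0.79 across the 18370 genes, which are not independent replicates, against 0.49 between simulated unchanged groups set against the same wild type libraries. Their covariance was 1.21 against 0.20 in the 40 simulations, in which 0 genes were shared. The shared genes include ccr7, lat, itk, gzma, nkl.2 and il2rb among the falls and c9, mhc1uba and il11a among the rises, but mhc1uba was at -0.67 in double mutants without the 4 libraries richest in liver transcripts. The prkdc mutants, with 0 genes called in edgeR, 1052 with an unadjusted p under 0.05 and 139 called by DESeq2, shared 0 calls with either, and their covariances were 0.16 with il2rga and 0.15 with double mutants against 0.20 in the simulations. Their correlations were 0.19 and 0.14 against 0.49, and 55.8% and 56.7% of genes had the same sign against 66.5% and 66.6%. The simulated groups held no changes, and changes in il2rga or double mutants alone would lower both measures. These lower values thus do not show prkdc mutants to be less alike than unchanged groups. The 3 wild type libraries are too few to be split between the comparisons, and the 0.49 of the simulations is what shared controls alone gave. Those 0 shared calls became 4 with il2rga and 5 with double mutants without wild type 2, 1 and 1 without wild type 3 or prkdc mutant 1, and 2 and 4 without il2rga mutant 2. The count of 840 was 258, 295 and 130 without wild type 1, 2 and 3, 525 without prkdc mutant 3, 537 and 262 without il2rga mutant 1 and 2, and 396 without double mutant 1. It was 0 with the liver covariate and 0 without the 4 libraries richest in liver transcripts, since edgeR then called 0 genes in double mutants.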

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

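The comparison of il2rga with prkdc mutants was planned before the data were examined, while the tests with a liver covariate and without the 4 libraries richest in liver transcripts were chosen only after the result was seen. In 4 of 36 gene lists the difference between the il2rga and the prkdc change against wild type passed in fry, adjusted over lists, whether or not either change passed by itself. For T cell genes the il2rga change minus the prkdc change had a median of -2.19, or -1.97 with genes at 0 counts held at their bound (adjusted p = 0.0369, range 2.5e-05 to 0.459 over 19 alternatives). For cytotoxic T and NK cell genes it was -2.09 (adjusted p = 0.000837, range 3.09e-08 to 0.0712). For immunoglobulin genes it was 4.25 (adjusted p = 0.0269, range 2.13e-08 to 0.306) and for p53 target genes 0.39 (adjusted p = 0.0238, range 0.0116 to 0.306). With an estimated correlation none of the 4 passed (camera, adjusted p = 0.459, 0.0619, 0.306 and 0.306 in that order). In the first 2 lists all 3 il2rga mutant libraries lay below all 3 prkdc mutant libraries, and in the last 2 all 3 lay above. The prkdc change had medians of -1.59, -0.32, -4.15 and -0.13 in these 4 lists, and the il2rga change -3.67, -3.64, 0.55 and 0.17. Beside the 0.39 of p53 target genes, the ribosomal protein and proliferation lists, which did not pass in fry, had medians of 0.37 and 0.88.

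In fry, the cytotoxic list passed without any 1 library (adjusted p from 0.000268 to 0.00999). The T cell list did not pass without wild type 1, any 1 prkdc mutant, il2rga mutant 1 or il2rga mutant 3 (adjusted p from 0.0502 to 0.125). The immunoglobulin list did not pass without wild type 1, any 1 prkdc mutant or il2rga mutant 1 (0.0502 to 0.125), nor the p53 target list without prkdc mutant 2, prkdc mutant 3 or il2rga mutant 1 (0.0783 to 0.109). With the liver covariate the adjusted p was 0.0433 for T cell, 0.0184 for cytotoxic, 0.0184 for immunoglobulin and 0.135 for p53 target genes. Without the 4 libraries richest in liver transcripts, which leaves 1 il2rga mutant, it was 0.17, 0.0712, 0.0238 and 0.0712. No list changed direction under any of the 19 alternatives. The 10 splits of these 6 libraries are too few for a share under 0.05, and the real split called 4 lists and 1244 genes where the highest of the others called 0 lists and 0 genes. Every other split mixes the groups, so any difference between them widens the spread there. The contrast thus does not tell genotype from another difference between the groups. Groups of 3 were not tested for a library far from the others.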

How the results depend on the processing

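The liver covariate and the setting without the 4 libraries richest in liver transcripts were chosen only after the result was seen, and the other alternatives before the data were examined. Loss of T cell genes in il2rga mutants against wild type was among the steadiest list results, passing under 18 of 19 alternatives (adjusted p up to 0.065), as did the cytotoxic list (up to 0.065). In double mutants T cell genes passed under 17 (up to 0.108), cytotoxic genes under 16 (up to 0.0883), DNA end joining genes under 8, B cell genes under 6, immunoglobulins under 5 and plasma cell genes under 3 (from 0.0206 to 0.736). In prkdc mutants T cell and immunoglobulin genes passed under 8 each (up to 0.2 and 0.336), and cytotoxic genes in double against prkdc mutants under 16 (up to 0.242). None of these lists changed direction. Counts of genes called were 0 for prkdc, 1066 for il2rga and 2628 for double mutants against wild type, 2717 for double against prkdc, 0 for double against il2rga and 1244 for il2rga against prkdc mutants, and 0 for the interaction (edgeR, with 1052, 1767 and 1123 at an unadjusted p under 0.05 where 0). In that order the DESeq2 Wald test called 139, 2400, 4078, 4176, 72, 2661 and 49, and the cause was not tested. limma voom with quality weights called 26 in prkdc and 2626 in il2rga mutants against wild type, and 3486 for il2rga against prkdc mutants, and the cause was not tested. Fits of only the groups compared called 1018 in double mutants against wild type, 236 for double against prkdc and 534 for il2rga against prkdc mutants. On as many libraries they called 942 in il2rga mutants against wild type, and the cause was not tested. No filter on low counts gave 793 for il2rga against prkdc mutants, with more genes in the adjustment. With the kidney tubule covariate 4117, 4388 and 2175 genes were called for double against wild type, double against prkdc and il2rga against prkdc mutants, and 2, 3 and 9 lists, with 1 list for the interaction, and the cause was not tested. Shared with the calls on all libraries were 2235, 2610 and 1168. A filter of 1 CPM in 3 libraries and leaving out haemoglobin genes kept every count of genes called within 1.5 times. Lists and shared calls were not counted under them.

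With the liver covariate edgeR called 5 genes in prkdc, 15 in il2rga and 0 in double mutants against wild type, 0 for double against prkdc and 4 for il2rga against prkdc mutants, 0 shared between il2rga and double mutants, and 1 list in double mutants against wild type and 0 against prkdc mutants. Of the calls on all libraries 1066 of 1066, 2481 of 2628, 2527 of 2717 and 1241 of 1244 kept their sign. Among the genes of the naming rule, those that reversed were, in double mutants against wild type, fga (-0.52), fgg (-0.52), vtg7 (-2.20), c3a.2 (-0.53), cd74b (0.015), hsd3b2 (-1.25), cyp17a1 (-2.17), zp2.1 (-1.58) and vtg2 (-4.92). Against prkdc mutants they were hsd3b2 (-0.57), cyp17a1 (-1.79), zar1 (-0.11), nkl.4 (0.70), fga (-0.65) and fgg (-0.56), and for il2rga against prkdc mutants fga (-0.26). None of these reversed values passed (edgeR, adjusted p from 0.425 to 0.988), and fga and fgg are themselves members of the liver list. The liver list is above 5 in 5 of the 6 libraries with the il2rga mutation, so the covariate takes up part of the difference between the groups. Without the 4 libraries edgeR called 22 genes in il2rga and 0 in double mutants against wild type, 0 for double against prkdc, 1 for double against il2rga and 16 for il2rga against prkdc mutants, and 0 shared, with 1 il2rga and 1 double mutant left, assumed to vary like the other groups. Lists were 0, 4 and 3 for prkdc, il2rga and double mutants against wild type, 3 for double against prkdc and 1 for double against il2rga mutants. Of the calls on all libraries 1059, 2490, 2587 and 1226 kept their sign, in the order given for the covariate. Among the genes of the naming rule, reversed were cish (-0.31), ctss2.1 (-0.023) and mhc1uba (-0.67) in double mutants against wild type, mhc1uba (-0.23) against prkdc mutants, and serpina1l (-0.091) for il2rga against prkdc mutants. Of the results for named genes 0 reversed under the other alternatives, and leaving out 1 library gave 6057 with the same call, 35 newly called and 1108 no longer called.

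camera with an estimated correlation called 0 lists for double against wild type, double against prkdc and il2rga against prkdc mutants. With the preset correlation of 0.01 it called 10, 9, 10, 9, 12, 11 and 12 lists in the order of the gene counts, as it takes 1 small correlation for every list. DESeq2 size factors called 3 lists for double against prkdc mutants, and the cause was not tested. Leaving out 1 library at a time gave 0 to 5, 160 to 1565, 490 to 3268, 382 to 2946, 0 to 5, 191 to 1664 and 0 to 1 genes in that order, and 0 to 3, 2 to 4, 2 to 8, 1 to 4, 0 to 3, 1 to 6 and 0 to 0 lists. The shared calls ranged from 0 to 4 for prkdc with il2rga, 0 to 5 for prkdc with double and 130 to 1235 for il2rga with double mutants.

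The replicate number as a block called 10 genes in prkdc mutants against wild type and 5 for double against il2rga mutants, 2 shared by prkdc and il2rga and 10 by prkdc and double mutants, and 3 lists for double against il2rga mutants, and the cause was not tested. Of 18 same-number pairs 6 had a correlation above 0.1, with a median of 0.066 against -0.017 for others. All 3 pairs of il2rga with double mutants were above 0.1 (0.132, 0.121 and 0.518), which the labels do not explain. But il2rga mutant 2 correlated more with double mutant 1 (0.418) and il2rga mutant 1 with double mutant 2 (0.212). The pair at 0.518, il2rga mutant 3 and double mutant 3, were each lowest of their group in the liver list, at 1.68 and 5.29 log2 CPM. Pairing was therefore not told apart from liver content, and the block may take up part of the latter. Depth and spread limit small changes, as 4% to 8% of simulated 2-fold and 44% to 64% of 4-fold changes were called.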

Other observations

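In this part, the tests of liver carry-over in dissection, of loss of il2rga as the source of liver transcripts, and of a haplotype and loss of prkdc for the class I genes were chosen only after the result was seen, as were the list of very long transcripts and the setting without 4 libraries. Of endothelial genes, the growth factor receptor kdr stood at 174 CPM in wild type and 181 CPM in prkdc mutants, and at 52.1 CPM in il2rga and 40.7 CPM in double mutants. It fell against wild type by 1.74 ± 0.24 in il2rga mutants and by 2.1 ± 0.24 in double mutants (log2, edgeR, adjusted p = 0.00585 and 0.00248). The clotting protein vwf fell by 1.64 ± 0.30 in double mutants (adjusted p = 0.00858), while egfl7, another endothelial gene, rose by 0.87 ± 0.20 in il2rga mutants (adjusted p = 0.0339). Of the 20 genes of the vascular endothelial list, 5 fell in double mutants over all genes tested and 6 adjusted over the list alone, with a median of -0.35, and the list did not pass (fry, adjusted p = 0.0988). Liver genes had a median of 6.88 in that comparison and very long transcripts -0.82.

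The chemokine ccl34a.4 rose by 4.20 ± 0.70 in il2rga and 4.42 ± 0.70 in double mutants (edgeR, adjusted p = 0.0108 and 0.00593). It and 1 more of 11 inflammatory cytokine genes rose in il2rga mutants over all genes tested and 7 adjusted over the list alone, with a median of 2.21 (fry, adjusted p = 0.092). In class II presentation, cd74a and ciita fell in double mutants by 2.17 ± 0.42 and 2.15 ± 0.46 (edgeR, adjusted p = 0.012 and 0.0161), and the 13 genes of the list had a median of -0.91 (fry, adjusted p = 0.123). Of 25 proliferation genes 6 rose in double mutants against wild type over all genes tested and 7 adjusted over the list alone, among them ccnb2 by 4.07 ± 0.91 (edgeR, adjusted p = 0.0217), with a median of 0.70 (fry, adjusted p = 0.271). The macrophage list members c1qc and mfap4 rose by 1.05 ± 0.22 and 2.42 ± 0.60 in il2rga mutants (edgeR, adjusted p = 0.0246 and 0.0421), and the 24 genes of the list did not pass, with a median of 0.69 (fry, adjusted p = 0.162). The distal tubule list member slc12a3, a salt transporter, rose by 1.61 ± 0.37 in il2rga mutants (edgeR, adjusted p = 0.0301), and the 16 genes of the list had a median of 0.50 (fry, adjusted p = 0.148). Liver genes had medians of 4.96 in il2rga and 6.88 in double mutants beside these changes, and very long transcripts -0.85 and -0.82.

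The first pattern is the 840 genes that changed alike in il2rga and double mutants against wild type, 303 higher and 537 lower. Liver and ovary carry-over as the whole source was not decided. Without the 4 libraries richest in liver transcripts the median of the 303 went from 1.07 to 0.93, a ratio of 0.872. That of the 537 went from -1.44 to -1.50, a ratio of 1.04, while the liver list went from 5.76 to 1.91. The genes were chosen as called in both mutants with the kept libraries included, which favours such ratios. Whichever 1 library of each mutant was kept, the ratio lay between 0.876 and 1.11 in log2 CPM. In il2rga mutant 3, low in liver transcripts, the medians of these chosen genes were 0.96 and -1.55, which rests on 1 library. Only 1 library per mutant group was left there, but with the liver covariate, on all 12 libraries, 0 calls were shared too. Why the calls ended was not tested. The ratios say less in double mutants, where double mutant 3 still carries liver transcripts and the liver list kept a ratio of 0.596. Fewer reads from long transcripts, as from RNA in poorer condition, stays open for the genes that fell, since the list of 53 very long transcripts had a median of -0.837 over both mutants. Loss of il2rga stays open too, and because all 6 libraries with fewer long transcripts carry that mutation, it was not tested apart from RNA condition.

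The second pattern is the liver transcripts. A candidate source is liver carried over in dissection. Each liver gene followed the rest of its list over the 12 libraries with a median correlation of 0.971, but any shared cause would give as much, so this does not favour carry-over. fga, the fibrinogen chain, reached 2015 CPM in double mutant 1. Against loss of il2rga acting alike in every animal stands 1 of the 6 libraries with the mutation, il2rga mutant 3, which lay inside the range of the other 6, but 1 library is too few to decide, so loss of il2rga cannot be told apart from carry-over.

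The third pattern is a set of class I genes, psmb8, psmb12, psmb13a, tap2a and mhc1uca, at 0 to 0.43 CPM in all 3 prkdc mutants and in wild type 3, and above 2 CPM in the other 8 libraries. Loss of prkdc is argued against, since 3 of the 6 libraries with that mutation, the double mutants, were above 2 CPM for psmb8, and wild type 3 was at 0.108 CPM. A general fall of antigen presentation genes is argued against by psme1, psme2, b2m and calr, whose median log2 fold change in prkdc mutants was -0.029. A haplotype that differs from the reference genome may be the source and stays open, as 0 of the 12 libraries were mixed, each having all 5 genes or none, though the 5 were chosen because they showed the pattern. Whether another haplotype's own copies were present was not tested. The class I gene mhc1uba, named among the rises of il2rga mutants, was not among the 5, and a haplotype was not tested for it.

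A hypothesis that alleles linked to the il2rga mutation account for local changes was tested with the order of genes in the GRCz12tu assembly. Of the 100 genes nearest to il2rga, 50 on each side, 13 were called in double mutants against wild type, or 13%, against a median of 15% in 1000 random windows. That share stood at percentile 32.6, below the 95th, which was 21%. This argues against a large local excess among genes that close, but a few linked changes would not show against that background.

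The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05, so real counts are given beside the highest of the other splits. The other splits mix the groups, so any difference between groups, whatever its source, widens the spread there and lowers their counts. In genes they were 0 and 0 for prkdc mutants against wild type, where as many were called in 10 of 10, 1066 and 0 for il2rga mutants, 2628 and 3 for double mutants, 2717 and 1 for double against prkdc mutants, and 0 and 0 for double against il2rga mutants. In lists they were 2 and 0, 2 and 1, 6 and 0, 1 and 1, and 0 and 2 in the same order, and as many as the 1 list of double against prkdc mutants were called in 2 of 10. For the interaction as many genes and lists, 0 in edgeR and fry, were called in all 40 of 40 splits, as a count of 0 must give, so this decides nothing about chance, and the highest other split had 0 genes and 2 lists, with 1123 genes at an unadjusted p under 0.05 in the real split, 49 called by DESeq2 and 0 by limma voom.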
